A study of Anguilla japonica with 6 samples.

How the data were processed

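RNA of 3 ovaries and 3 testes of farmed Japanese eels at the silver stage was sequenced by the authors on an Illumina instrument from libraries made with the NEBNext Ultra RNA kit after TRIzol extraction, and full-length transcripts of both tissues were sequenced by PacBio Iso-seq. Per the labels, the processing used CASAVA 1.8, fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3, without stating the part of each, and the quantifier of the values used here and the genome build are not given in the sources used here.

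One table was used, with 35011 full-length transcripts, 22549 built from ovary and 12462 from testis long reads. Per the file headers, the deposited values of each library are read counts and FPKM per transcript, and the table also gives the deposited transcript length in bases and annotations. The read counts are called estimated counts here because most were not whole numbers. The deposited estimated counts were whole numbers for 26.5% to 31.6% of the transcripts of a library, and how the authors divided reads shared by transcripts is not given in the sources used here. The plan had foreseen whole counts or FPKM alone. As counts of this kind serve the count models, they were rounded to whole numbers and tested by the plan's model for counts. The deposited FPKM are scaled by the authors for library size and transcript length, and their sums differed between libraries, from 721650 to 1312673. Library totals ran from 11913969 to 18508307 counts, and counting intervals and floors cover counting error only. No table of the authors' own comparisons and no mark of transcription factors was used here, so the planned results that needed them were not run.

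A gene symbol was taken from the annotation of 31472 transcripts, with 9331 distinct symbols, from the protein hit for 31080 and the nucleotide hit for 392. Of these symbols, 6436 had 2 or more transcripts. Since rows of the table are transcripts, estimated counts and FPKM were also summed per symbol, called genes in the text, with transcripts without a symbol kept single (12870 units). Of the tested units 2831 had no symbol, among them 8 of the oocyte list and 5 of the leukocyte list, which were placed there by their annotation. List tests over genes include them. This summing was chosen after the data were seen, and the rule for named genes, which speaks of genes, was applied to it.

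Differences were tested with edgeR 4.0.16 (TMM normalization, filterByExpr by group, glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, coded testis minus ovary, with the tissue as the only term. A Benjamini-Hochberg adjusted p under 0.05 was called. After filtering, 30738 transcripts and 12081 genes were tested. Shares of counts and numbers of expressed transcripts were compared by exact two-sided permutation tests, whose smallest p is 0.1 with 3 against 3. Fixed lists, with at least 5 tested members, and annotation terms with 10 to 300 members were tested by camera of limma 3.58.1 on log2 CPM with a prior count of 2, against all other tested units and with a preset correlation of 0.01. Of 25 lists, 23 were tested over transcripts and 22 over genes, adjusted over the lists, and adjusted p values with the correlation estimated from the data are given beside the calls. Transcripts of one gene are not independent, so camera p values over transcripts with the preset correlation do not measure variation between fish. As an alternative, fry of limma tested whether a list's members move on balance one way, without comparing them with other genes. Terms were also tested by one-sided Fisher exact tests with all tested, annotated units as background. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.

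The tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls among called genes with all values of one tissue above all of the other, a mean of at least 10 FPKM in the higher tissue and an informative symbol, up to 4 members per list with the smallest adjusted p, the 3 most abundant genes of each tissue, and a fixed set of genes of sex and germ cells, 122 genes in all. Of the fixed set, amh, gsdf, sox9, cyp19a1, cyp11a1, cyp11c1, fshr, lhcgr, ar and esr1 matched no transcript by symbol and were not analysed here. Some genes that the rule names are not reported here. Genes named outside the rule are said to have been named after their values were seen. Folds against a tissue without any count are bounds against a floor of 3 counts over its 3 libraries, and ratios with 1 to 3 counts have exact 95% binomial intervals.

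On simulated data with 25% of transcripts changed, the model called 49.7% of transcripts changed 16-fold and 92.1% of those changed 256-fold, with 2.87% of calls false, and for genes 91.3% and 98.5%, with 2.59% false. With 200 changed transcripts, edgeR called 0 at any fold, and with 200 changed genes 82% of those changed 16-fold. Each transcript or gene was simulated independently, without reads shared between transcripts and without a library that stands apart. These rates may therefore not hold for the real libraries. Testis and ovary came from different fish with like replicate numbers. The deviations from the tissue mean of libraries with the same number correlated at 0.0151, -0.000568 and -0.00204 over transcripts and at -0.0255, 0.00827 and -0.0259 over genes, so the numbers were taken not to pair the libraries.

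Alternatives were other normalizations (upper quartile, quantile), limma on log2(TPM + 1), DESeq2 1.42.0, limma-voom, limma on log2 FPKM with pseudocounts of 1, 0.1 and 0.01, limma without trend, limma with array weights, other filters on low values, a replicate block, and leaving out each library in turn. Counts summed per symbol, with their own alternatives, and the fit without ribosomal protein and egg envelope transcripts were chosen after seeing the data.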

Results

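The ovary and the testis of the Japanese eel (Anguilla japonica) were compared by RNA sequencing in farmed fish at the silver stage, the stage that precedes the spawning migration, whose gonads were differentiated but immature and which had received no hormone. There were 3 ovaries and 3 testes, each from a different fish. Short reads had been counted against full-length transcripts built from long reads of the same 2 tissues. The ovary libraries held 17261144, 15096728 and 18508307 counts and the testis libraries 13616804, 13330256 and 11913969. In the table, 35011 transcripts carried 9331 distinct gene symbols, so each result is given for transcripts, the unit of the table, or for genes, whose transcripts were summed by symbol. Transcripts without a symbol stay single and are counted among the genes unless said otherwise. Values below are FPKM as mean ± SD over 3 fish per tissue, fold changes are testis over ovary, and adjusted p values are from edgeR unless another test is named.

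The question was how the transcriptomes of the 2 immature gonads differ. Of 37 genes of meiosis 29 were higher in testis and 1 in ovary, and of 49 genes of the sperm flagellum 35 and 1. Hsf2bp, a meiotic recombination factor, stood at 1.18 ± 0.335 in ovary and 182 ± 24.3 in testis (adjusted p = 0.0006), and drc7, a part of the tail's dynein regulatory complex, at 0.403 ± 0.251 and 65.8 ± 2.82 (adjusted p = 0.000918). Of 22 oocyte genes with a symbol 17 were higher in ovary and 2 in testis. Bmp15, a growth factor made by the oocyte, stood at 62.4 ± 4.83 and 4.17 ± 0.586 (adjusted p = 0.000684), and vldlr, the receptor that takes up egg yolk precursor, at 302 ± 71.0 and 17 ± 1.02 (adjusted p = 0.000831). Dmrt1, a transcription factor of the male gonad, stood at 2.33 ± 1.58 in ovary and 67.0 ± 16.2 in testis (adjusted p = 0.00165). Of 70 ribosomal protein genes 58 were higher in testis and 1 in ovary, the rpl7-like gene rpl7l1, named after its value was seen. The list tests of meiosis, flagellum, oocyte and ribosomal protein transcripts gave calls that were lost with the correlation estimated from the data (adjusted p = 0.257, 0.275, 0.275 and 0.466 with an estimated correlation).

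Egg envelope transcripts, which encode the zona pellucida proteins around the egg, took 20.9% ± 1.56 of the counts in ovary and 1.45% ± 1.71 in testis. Within the testis libraries this share was 0.115%, 3.37% and 0.846% for replicates 1, 2 and 3, and the mean without replicate 2 was 0.480%. Ribosomal protein transcripts took 4.04% ± 0.349 in ovary and 19.2% ± 8.29 in testis, where replicate 1 held 9.66% and the other two 24.8% and 23.1%. Only 8 mitochondrially encoded transcripts, of 5 genes, matched by symbol, so their share is not that of all mitochondrial transcripts. They took 0.00512% ± 0.000918 in ovary and 0.648% ± 0.525 in testis. Their share was 1.2%, 0.586% and 0.156% in testis replicates 1, 2 and 3, with a mean of 0.371% without replicate 1. Each of these 3 differences separated all ovaries from all testes, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. The 10 most abundant transcripts of a library took 11.7% ± 1.95 of the counts in ovary and 8.58% ± 2.63 in testis (exact permutation p = 0.3).

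**Figure D1:**
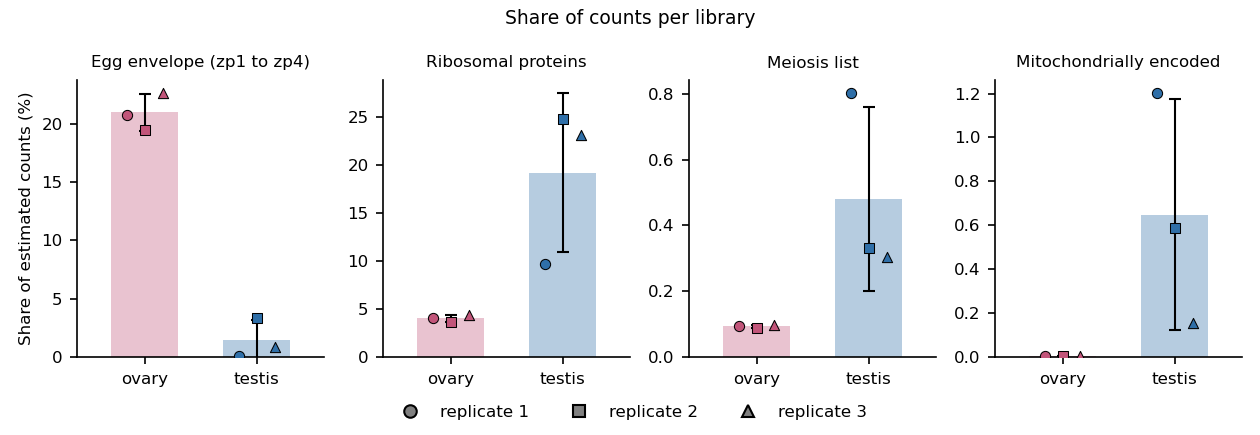
Percent of each library's estimated counts in egg envelope, ribosomal protein, meiosis and mitochondrially encoded transcripts, with one point per library, bars for the mean and error bars for the SD of 3 libraries, on a scale of its own for each group. Egg envelope transcripts took 20.9% in ovary and 1.45% in testis, and ribosomal protein transcripts 4.04% and 19.2%. In ovary, sycp2l, named after its value was seen, held 38.7% of the meiosis counts.

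Across genes, the libraries grouped by tissue. Rank correlations between ovaries ran from 0.903 to 0.922 and those between an ovary and a testis from 0.453 to 0.534. Testis replicate 1 stood apart, with correlations of 0.790 and 0.779 to replicates 2 and 3, which correlated at 0.920 with each other. The first principal component held 70.9% of the variance and separated the tissues, and the second held 12.5%. Single transcripts varied more between fish than genes did, with correlations of 0.523 to 0.615 between ovaries and 0.545 to 0.781 between testes.

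**Figure D2:**
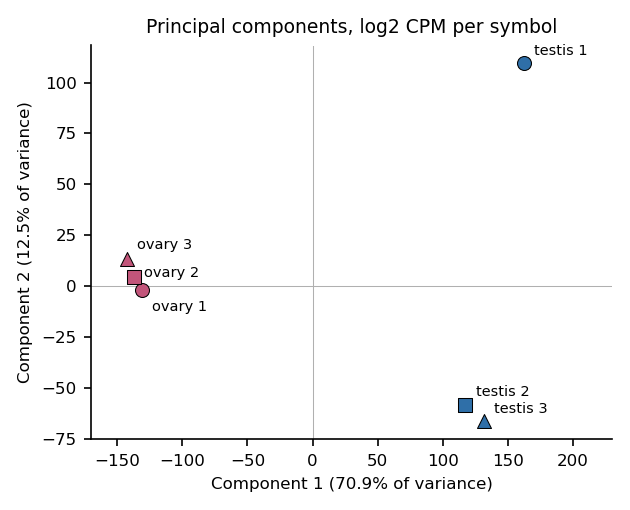
Principal components of log2 CPM over all tested genes, one point per library, coloured by tissue. The first component, with 70.9% of the variance, separates ovary from testis, and testis replicate 1 lies apart from the other two testes.

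Of 12081 genes tested, 3044 were higher in testis and 2600 higher in ovary, 5644 in all. Those with a symbol were 9250, with 2200 and 2087, and those without one 2831, with 844 and 513. Of the 5644, 5457 differed by at least 1 on the log2 scale, and 59.6% of tested genes had values that did not overlap between the tissues, where chance gives 10%. Of 30738 transcripts tested, 1924 were higher in testis and 1352 in ovary, 3276 in all. The majority turned with limma on log2(TPM + 1), with 1707 and 2259, and with DESeq2, with 4882 and 5025, and was 1053 and 1023 with limma-voom. With edgeR no transcript was called when ovary replicate 1, ovary replicate 2, ovary replicate 3, testis replicate 2 or testis replicate 3 was left out (8050, 8171, 8493, 8111 and 7992 with an unadjusted p under 0.05), and 1439 were called without testis replicate 1. With all libraries DESeq2 called 9907, limma on log2(FPKM + 1) 4759 and limma-voom 2076. Each transcript count below shares this limit. Testis held 53.9% of the called genes with edgeR, 59.5% with limma on log2(FPKM + 1) and 43.6% with limma on log2(TPM + 1). The median log2 fold change of all genes was 0.10, 0.26 and -0.16 in these fits, and 0.28 with edgeR and upper quartile scaling.

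The 10 largest rises in testis included nefh, star, zswim2, rec8, ccdc166, cahz, col28a1, wasf1 and eef1a1. Nefh, a neurofilament, star, which carries cholesterol into mitochondria for steroid synthesis, and zswim2 had no count in any ovary and were at least 1403-fold, at least 1051-fold and at least 833.8-fold higher in testis, against a floor of 3 counts over the ovaries. The bounds for nefh and star rested on single testes, being 120 for nefh without testis replicate 1 and 344 for star without testis replicate 3. Without ovary replicates 1 and 3 the bounds were 927 and 892 for nefh, 694 and 668 for star and 551 and 530.4 for zswim2. Nefh was not called with limma-voom, limma on log2(FPKM + 1) or limma on log2(TPM + 1) (adjusted p = 0.0602, 0.0572 and 0.0801). Rec8, a cohesin of meiosis, had 3 counts in the ovaries and a ratio of 2585 (95% counting interval 884 to 12540), which was 554 without testis replicate 1, 1708 without ovary replicate 1 and 4933 without ovary replicate 3. Ccdc166 had 2 counts in the ovaries and a ratio of 1844 (510 to 15240), which was 320 without testis replicate 1 and 1218 without ovary replicate 1. Without ovary replicate 3 no ovary count remained and the bound was at least 782.1-fold. Cahz, a carbonic anhydrase of fish red blood cells, stood at 1312 ± 2088 in testis, with 3723 in replicate 1 and 81.0 and 132 in the other two, and 1.27 ± 0.831 in ovary, and col28a1, a collagen, at 57 ± 21.8 and 0.05 ± 0.0866. Wasf1, an actin regulator, stood at 67.1 ± 38.6 and 0.0600 ± 0.0656, and eef1a1, a translation elongation factor, at 805 ± 586 and 0.833 ± 0.591. Their adjusted p values ran from 0.00106 for eef1a1 to 0.0186 for nefh.

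The 10 largest falls, genes higher in ovary, were in ighv5-51, prlh, clec4m, foxn5, sox19a, hcar2, sox3, mos, tenm2 and magi3. Ighv5-51, annotated as an immunoglobulin variable segment, had no count in any testis and was at least 594.9-fold lower there than in ovary. This bound was 254 without ovary replicate 1, 386 without testis replicate 1 and 391 without testis replicate 2. Clec4m, a lectin, had 3 counts in the testes and a ratio of 746 in favour of ovary (95% counting interval 255 to 3619). The ratio was 184 without ovary replicate 1, 1138 without ovary replicate 3, 484 without testis replicate 1 and 1470 without testis replicate 2, and clec4m was not called with limma-voom (adjusted p = 0.0813). Foxn5, a forkhead factor, stood at 1390 ± 233 in ovary and 3.43 ± 3.88 in testis, and sox3, a factor of germ cells and neural tissue, at 209 ± 14.5 and 1.26 ± 1.21. Mos, the kinase that arrests the egg in meiosis, stood at 213 ± 60.3 and 1.37 ± 0.953, and prlh, annotated as prolactin-releasing peptide, at 112 ± 61.3 and 0.120 ± 0.208. Sox19a, hcar2, tenm2 and magi3 had log2 fold changes of -8.75, -8.27, -7.48 and -7.32. Adjusted p values of these genes ran from 0.00122 for hcar2 to 0.0050 for foxn5.

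**Figure D3:**
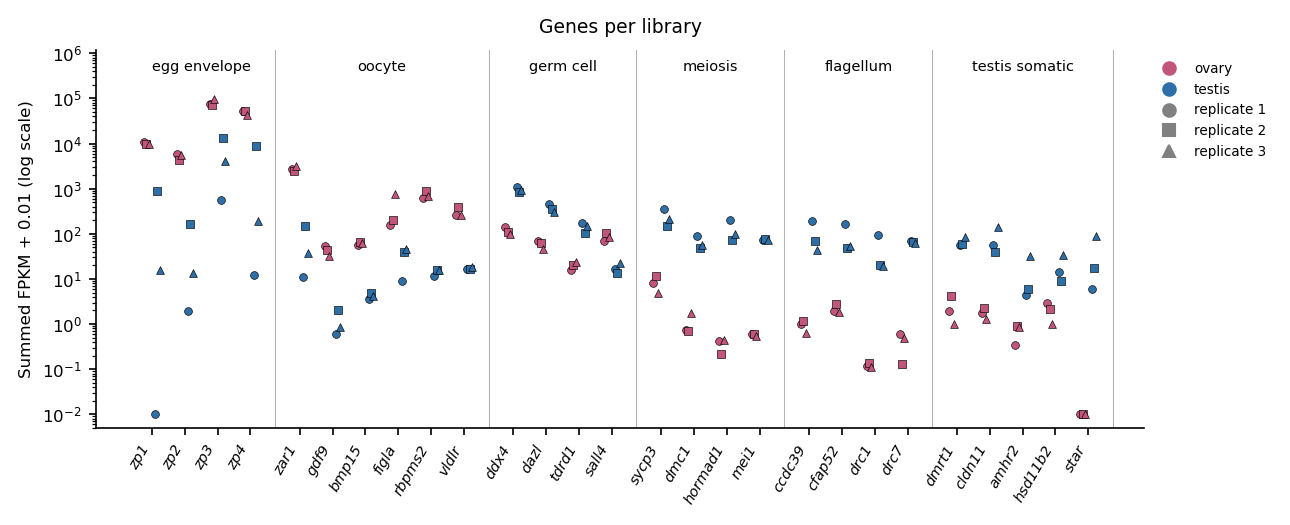
FPKM summed per gene, plus 0.01, of selected named genes on a log axis, with one point per library, coloured by tissue and shaped by replicate. The meiosis and flagellum genes shown lie higher in the 3 testes and the oocyte genes shown higher in the 3 ovaries.

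Most oocyte genes were higher in ovary. Of 22 tested with a symbol, 17 were higher in ovary, 2 in testis and 3 were not called, with a median log2 fold change of -4.59. The list also held 8 transcripts without a symbol, of which 5 were higher in ovary and 3 not called. Ccnb1, the cyclin that drives entry into division, stood at 2949 ± 1211 in ovary and 85.2 ± 40.5 in testis, and zar1, a maternal factor of the early embryo, at 2804 ± 379 and 65.3 ± 72.0. Larp6, an RNA-binding protein, stood at 1118 ± 209 and 14.9 ± 7.31, and rbpms2, an RNA-binding protein of the oocyte's Balbiani body, at 727 ± 134 and 14.5 ± 2.60 (adjusted p from 0.000684 for rbpms2 to 0.00571 for zar1). Gdf9, the oocyte partner of bmp15, figla, a transcription factor of the early oocyte, and gtf3a, which drives 5S ribosomal RNA in oocytes, had log2 fold changes of -5.44, -3.70 and -3.16. The 2 genes of the list higher in testis were tdrd15 and eef1ao, named after their values were seen, by 5.97 and 2.51. Adjusted over the list alone, 19 genes with a symbol were higher in ovary and 2 in testis. Of 102 oocyte transcripts, 28 were higher in ovary, 4 in testis and 70 not called (56 and 5 adjusted over the list alone), with a camera adjusted p of 4.79e-13. The oocyte list had adjusted p = 0.275 with an estimated correlation.

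Of the 4 egg envelope genes, zp2 and zp3 passed the test and zp1 and zp4 did not, alone or adjusted over the list alone. Zp3, the most abundant gene in ovary, stood at 79671 ± 13218 there and 5953 ± 6447 in testis (adjusted p = 0.0338), and zp2 at 5212 ± 790 and 59.7 ± 90.5 (adjusted p = 0.0157). Zp4 stood at 48779 ± 4702 and 2950 ± 4936 (adjusted p = 0.0988) and zp1 at 10012 ± 622 and 297 ± 502 (adjusted p = 0.123). Both passed without testis replicate 2, at 0.0140 and 0.0290, and all 4 genes passed with limma-voom and with limma on log2(FPKM + 1). Zp3 was not called without ovary replicates 1, 2 or 3 (adjusted p = 0.0910, 0.0732 and 0.0918) or testis replicate 3 (0.121), nor zp2 without testis replicate 3 (0.0553). Of 286 egg envelope transcripts, 49 were higher in ovary, none in testis and 237 not called (112 and none adjusted over the list alone), with a camera adjusted p of 6.13e-28. These transcripts belong to only 4 genes, too few for a list test over genes. The preset correlation treats them as nearly independent, so this p value does not measure variation between fish. The egg envelope list had adjusted p = 0.275 with an estimated correlation.

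Genes of meiosis were higher in testis for 29 of 37, higher in ovary for 1 and not called for 7. Hormad1, which marks unpaired chromosome axes, stood at 0.350 ± 0.122 in ovary and 125 ± 66.9 in testis, and sycp3, of the axis that holds paired chromosomes, at 8.15 ± 3.34 and 242 ± 111. Dmc1, the meiotic recombinase, stood at 1.04 ± 0.583 and 66.0 ± 21.8, and mei1 at 0.573 ± 0.0379 and 73.6 ± 3.37 (adjusted p from 0.000684 for hormad1 and mei1 to 0.000949 for sycp3). Cntd1, a crossover factor, rose by 8.91 on the log2 scale. The gene higher in ovary was sycp2l, named after its value was seen, which fell by 5.61 in testis. It was matched by its symbol as a paralog of the listed sycp2, and held 38.7% of the list's counts in ovary. Those higher in ovary were 3 genes without testis replicate 1 and none without testis replicate 3. Adjusted over the list alone, 29 genes were higher in testis and 2 in ovary. Of 125 meiosis transcripts, 48 were higher in testis, 1 in ovary and 76 not called (67 and 6 adjusted over the list alone), with a camera adjusted p of 2.19e-13. The meiosis list had adjusted p = 0.257 with an estimated correlation.

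Genes of the sperm flagellum were higher in testis for 35 of 49, higher in ovary for 1 and not called for 13. Ccdc39, which sets the repeat length of the axoneme, stood at 0.927 ± 0.255 in ovary and 101 ± 77.8 in testis, cfap52 at 2.17 ± 0.562 and 88.4 ± 65.6, and drc1 at 0.113 ± 0.0153 and 45.4 ± 44.1 (adjusted p = 0.000993, 0.00124 and 0.00115). The gene higher in ovary was tekt3, a filament protein of cilia, named after its value was seen, which fell by 3.80. In ovary 2 genes were higher without testis replicate 1. Adjusted over the list alone, 35 genes were higher in testis and 1 in ovary. Of 125 flagellum transcripts, 34 were higher in testis, 1 in ovary and 90 not called (62 and 1 adjusted over the list alone), with a camera adjusted p of 2.82e-11. The flagellum list had adjusted p = 0.275 with an estimated correlation. In testis replicate 1, flagellum genes stood higher than the mean of the other testes by a median of 1.86 on the log2 scale and meiosis genes by 1.15.

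Germ cell genes shared by the sexes differed gene by gene. Ddx4 (vasa), a helicase of germ cells, stood at 118 ± 23.8 in ovary and 953 ± 135 in testis, dazl, an RNA-binding protein of germ cells, at 59.3 ± 11.5 and 375 ± 85.7 (adjusted p = 0.00168 and 0.00213). Tdrd1, of the piRNA pathway, stood at 20.1 ± 3.90 and 141 ± 33.8 (adjusted p = 0.00191). Sall4, a factor of stem and germ cells, was higher in ovary, at 86.8 ± 17.2 against 17.3 ± 4.67 (adjusted p = 0.00155). Of 23 genes, 11 were higher in testis, 6 in ovary and 6 not called (13 and 6 adjusted over the list alone), and 7 were higher in testis without ovary replicate 2. Of 143 transcripts, 7 were higher in testis, 7 in ovary and 129 not called, the called ones being as many adjusted over the list alone. This list was not called (camera adjusted p = 0.402).

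Of 20 fixed somatic genes of the testis, 7 matched the table, and 5 of these 7 were higher in testis. Cldn11, a junction protein of Sertoli cells, stood at 1.76 ± 0.5 in ovary and 78.6 ± 54.7 in testis (adjusted p = 0.00141), and hsd11b2, of 11-ketotestosterone synthesis, at 2.01 ± 0.964 and 18.9 ± 12.7 (adjusted p = 0.0101). With dmrt1, amhr2 (0.680 ± 0.304 and 14.2 ± 15.8, adjusted p = 0.0148) and wt1, named after its value was seen, these made 5 of 7 genes, also adjusted over the list alone, while ptch1 and nr5a1 were not called. Without ovary replicate 1 or testis replicate 3, and with limma-voom, the count was 3. Without these libraries amhr2, the receptor of anti-Mullerian hormone, had adjusted p = 0.0582 and 0.0542 (0.0597 with limma-voom). Of 11 transcripts, 4 were higher in testis, none in ovary and 7 not called (8 and none adjusted over the list alone), with a camera adjusted p of 9.51e-05. The testis somatic list had adjusted p = 0.278 with an estimated correlation.

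Of 18 fixed genes of the ovary's somatic cells, 8 matched the table, and none of these 8 was higher in ovary. Esr2, an estrogen receptor (1.61 ± 0.291 in ovary and 31.4 ± 17.7 in testis, adjusted p = 0.00209), nr5a2, a nuclear receptor (0.913 ± 0.327 and 12.6 ± 10.4, 0.0120), and fsta, an activin antagonist (0.253 ± 0.297 and 6.40 ± 2.29, 0.0257), were higher in testis, and the same number passed adjusted over the list alone. Nr5a2 was not called with limma-voom (adjusted p = 0.0522). Fsta was not called without ovary replicate 1, testis replicate 2 or testis replicate 3 (adjusted p = 0.1, 0.0753 and 0.0575). Foxl2, a factor of granulosa cells, stood at 1.72 ± 0.509 and 1.23 ± 1.56 (adjusted p = 0.632) and runx1 at 12 ± 0.544 and 35 ± 20.4 (0.0845, and 0.00261 without testis replicate 1). Of 17 transcripts, 1 was higher in testis, none in ovary and 16 not called (3 and none adjusted over the list alone). The list was not called (camera adjusted p = 0.0901) but was called higher in testis without testis replicate 1, with 5 genes higher and adjusted p = 0.00845.

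Steroid genes went both ways. Star was higher in testis, at 38.4 ± 46.3 against no count in ovary, while hsd17b12, hsd17b12a, srd5a1 and cbr1, enzymes that reduce steroids and other substrates, were higher in ovary. So were hsd3b and stard3, named after their values were seen (log2 fold change -3.40 and -1.95, adjusted p = 0.00911 and 0.0055). Hsd17b12a stood at 89.3 ± 9.34 against 11.5 ± 6.67 and srd5a1, the 5-alpha-reductase, at 42.7 ± 8.78 against 7.67 ± 2.23 (adjusted p = 0.0015 and 0.0026). Cyp17a1, of androgen synthesis, stood at 9.90 ± 13.4 in ovary and 47.7 ± 28.6 in testis (adjusted p = 0.0535, and 0.0210 without ovary replicate 2, called in 10 of 20 alternatives). Of 11 genes, 2 were higher in testis, 6 in ovary and 3 not called (3 and 6 adjusted over the list alone). Of 25 transcripts, 2 were higher in testis, 5 in ovary and 18 not called (3 and 5 adjusted over the list alone). This list was not called (camera adjusted p = 0.278). Over the genes the median log2 fold change was -1.95.

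Among receptors, bmpr1b, a receptor of bone morphogenetic proteins, was higher in testis (1.04 ± 0.278 against 11.9 ± 5.10, adjusted p = 0.00359) and its relative bmpr1a in ovary (23.9 ± 5.12 against 4.88 ± 1.49, adjusted p = 0.0018). Pgr, the nuclear progestin receptor, was higher in testis (2.68 ± 1.16 against 25.8 ± 16.8, adjusted p = 0.00457), while paqr7b and paqr5a, membrane progestin receptors named after their values were seen, with acvr1c, were higher in ovary (log2 fold change -1.67, -1.88 and -2.80). Of 22 genes, 8 were higher in testis, 4 in ovary and 10 not called, with as many adjusted over the list alone. Those higher in testis were 5 without ovary replicate 1, and those higher in ovary 2 without ovary replicate 1 or 3. Of 82 transcripts, 8 were higher in testis, 1 in ovary and 73 not called (9 and 1 adjusted over the list alone). This list was not called (camera adjusted p = 0.287).

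**Figure D4:**
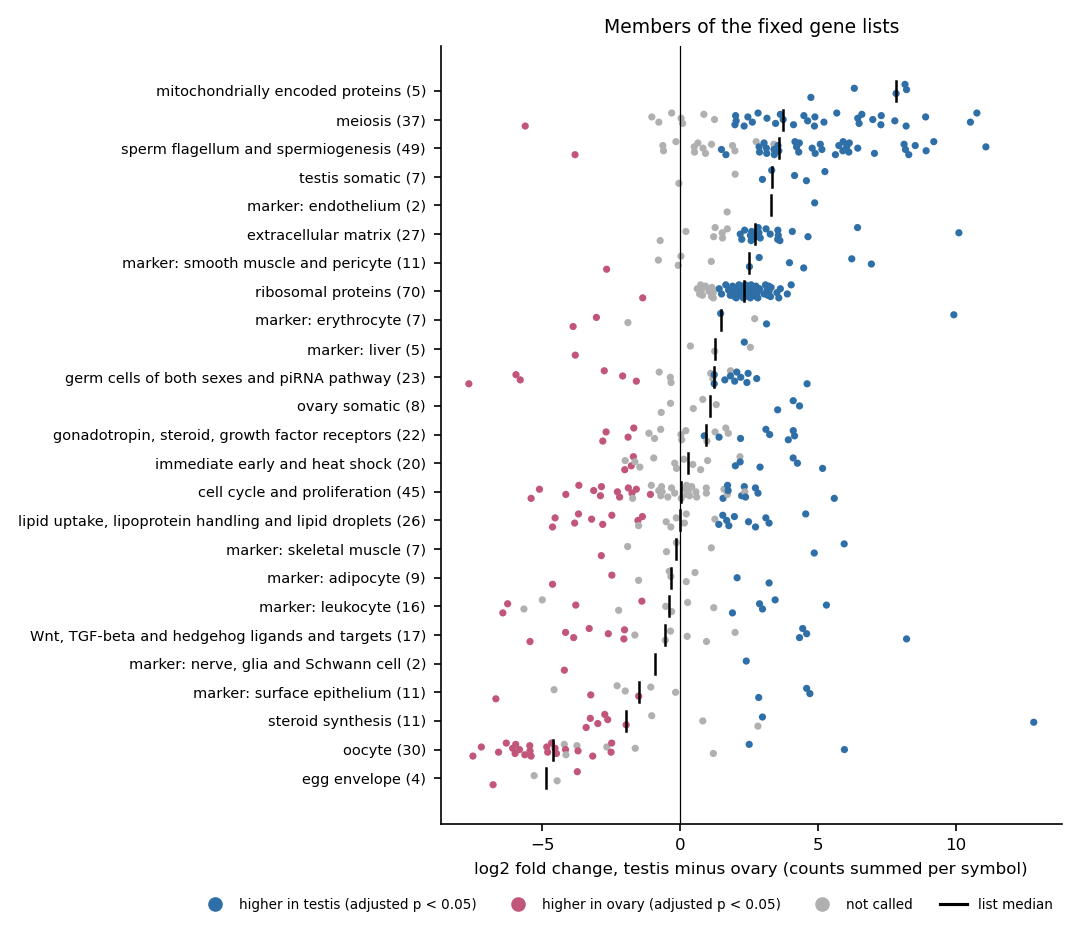
Log2 fold change, testis over ovary, of each member of the fixed gene lists with counts summed per gene, coloured by whether it was higher in testis, higher in ovary or not called, with a bar at the list's median and the number of tested members in parentheses, which for the oocyte and leukocyte lists takes in 8 and 5 transcripts without a symbol. The median was 3.75 for meiosis, 2.33 for ribosomal protein and -4.59 for oocyte genes.

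Cell cycle genes differed gene by gene. Ccne1, the cyclin of entry into DNA synthesis, stood at 147 ± 39.7 in ovary and 10.1 ± 4.93 in testis, ccnb2 at 809 ± 326 and 84.4 ± 54.6, and cdc20, an activator of the anaphase-promoting complex, at 1313 ± 235 and 49.1 ± 26.9 (adjusted p = 0.000949, 0.00237 and 0.00112). Mcm2, mcm3 and mcm6, of the replicative helicase and named after their values were seen, rose in testis by 2.24, 2.38 and 5.60 on the log2 scale, while cdt1, cdc45 and tk1, also of DNA replication and named likewise, were higher in ovary (log2 fold change -3.13, -1.74 and -1.58). Of 45 genes, 9 were higher in testis, 13 in ovary and 23 not called, with as many adjusted over the list alone. Those higher in testis were 5 without ovary replicate 1 or 2, 6 with limma-voom and 2 with limma on log2(TPM + 1). Those higher in ovary were 8 without ovary replicate 2 or testis replicate 3, 23 with array weights and 24 without testis replicate 1, in which this list stood higher than in the other testes by a median of 1.76. Of 192 transcripts, 5 were higher in testis, 19 in ovary and 168 not called (6 and 22 adjusted over the list alone). This list was not called (camera adjusted p = 0.164) except without testis replicate 1, when it was lower in testis (adjusted p = 0.0323). The median log2 fold change of the genes was 0.05, their mean -0.24, and the median was -1.41 without testis replicate 1.

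Most genes of the extracellular matrix were higher in testis. Col6a1 and col6a2, chains of collagen VI, stood at 4.65 ± 1.87 and 3.06 ± 0.838 in ovary and at 29.2 ± 23.6 and 41.9 ± 24 in testis, tnc, tenascin C, at 1.5 ± 0.271 and 21.4 ± 15.7, and loxl2b, a collagen cross-linking enzyme, at 0.133 ± 0.0115 and 4.11 ± 1.30 (adjusted p from 0.00227 for loxl2b to 0.00478 for col6a1). Of 27 genes, 20 were higher in testis, none in ovary and 7 not called (21 and none adjusted over the list alone). The count was 12, 13 and 11 without ovary replicates 1, 2 and 3. Of 54 transcripts, 9 were higher in testis, 1 in ovary and 44 not called (25 and 1 adjusted over the list alone), with a camera adjusted p of 6.37e-07. The matrix list had adjusted p = 0.354 with an estimated correlation. The share of counts in matrix transcripts was 0.151%, 0.261% and 0.844% in testis replicates 1, 2 and 3.

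Lipid genes also went both ways. Vldlr, scarb1, a lipoprotein receptor (85.0 ± 15.4 in ovary and 6.10 ± 1.13 in testis, adjusted p = 0.000903), and cidec, of the lipid droplet (89.5 ± 4.33 and 19.2 ± 1.71, 0.00103), were higher in ovary. Lrp1b and lrp1, large receptors of the same family named after their values were seen, rose in testis by 4.56 and 3.12 on the log2 scale. Of 26 genes, 10 were higher in testis, 9 in ovary and 7 not called, with as many adjusted over the list alone. Those higher in testis were 4, 3, 4 and 6 without ovary replicates 1, 2 and 3 and testis replicate 3, and 4 with limma on log2(TPM + 1). Of 103 transcripts, 4 were higher in testis, 9 in ovary and 90 not called (10 and 26 adjusted over the list alone), with a camera adjusted p of 0.0249 toward ovary. The lipid list had adjusted p = 0.257 with an estimated correlation and 0.774 with counts summed per gene, where its median log2 fold change was 0.01 against -1.60 over transcripts.

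Of 17 signalling genes of the Wnt, TGF-beta and hedgehog families, 4 were higher in testis, 7 in ovary and 6 not called (4 and 8 adjusted over the list alone). Id2, an inhibitor of basic helix-loop-helix factors, stood at 0.513 ± 0.327 in ovary and 183 ± 147 in testis, and frzb, a secreted Wnt antagonist, at 0.547 ± 0.146 and 14.4 ± 8.62 (adjusted p = 0.00177 and 0.00285). Fsta and tgfb3, the latter named after its value was seen, were the others higher in testis. Those higher in ovary were led by bmp15 and gdf9, also in the oocyte list, and were 4 without ovary replicates 1, 2 or 3 or testis replicate 2. Of 26 transcripts, 2 were higher in testis, 6 in ovary and 18 not called (3 and 6 adjusted over the list alone), with a camera adjusted p of 0.0387 toward ovary. The signalling list had adjusted p = 0.466 with an estimated correlation, 0.0692 on log2(FPKM + 0.1), 0.406 with counts summed per gene, 0.0523 without ovary replicate 3 and 0.108 without testis replicate 1.

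Ribosomal protein genes were higher in testis for 58 of 70, higher in ovary for 1 and not called for 11 (60 and 1 adjusted over the list alone). The gene higher in ovary was rpl7l1, named after its value was seen, an rpl7-like gene that the list's symbol pattern took in. Rpl15 stood at 759 ± 194 in ovary and 10664 ± 4821 in testis, rpl29 at 501 ± 216 and 5066 ± 1693, and rps4x at 621 ± 58.0 and 4105 ± 882 (adjusted p = 0.00367, 0.00267 and 0.00377). The count was 22, 26 and 37 without ovary replicates 1, 2 and 3. Of 131 transcripts, 10 were higher in testis, 1 in ovary and 120 not called (24 and 1 adjusted over the list alone), with a camera adjusted p of 2.88e-09. The ribosomal list had adjusted p = 0.466 with an estimated correlation.

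The mitochondrially encoded genes that matched by symbol were higher in testis for 5 of 5, also adjusted over the list alone. Mt-atp6, of ATP synthase, stood at 71.9 ± 5.90 in ovary and 6825 ± 3708 in testis, and mt-nd4, of complex I, at 4.02 ± 1.43 and 1146 ± 1486 (adjusted p = 0.00115 and 0.0040), with mt-nd1, mt-nd2 and mt-nd5, the last named after its value was seen. The count was 2 without ovary replicates 1, 2 or 3, where mt-nd1 had adjusted p = 0.0585, 0.0712 and 0.0752 and mt-nd2 0.0736, 0.0599 and 0.0757. It was 3 with limma without trend and 2 with limma-voom and with limma on log2(TPM + 1), and DESeq2 gave an adjusted p for 3 of the genes, all higher in testis. The median log2 fold change was 7.84, and 3.55 without testis replicate 1. Of 7 transcripts, 3 were higher in testis, none in ovary and 4 not called (6 and none adjusted over the list alone), with a camera adjusted p of 0.000479. The mitochondrial list had adjusted p = 0.365 with an estimated correlation.

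Immediate early and heat shock genes, which respond to handling, differed gene by gene. Jun, a transcription factor of the early response, stood at 20 ± 4.44 in ovary and 108 ± 21.1 in testis, klf2 at 0.753 ± 0.276 and 15.6 ± 10.1, and gadd45b, induced by stress, at 11 ± 4.75 and 97.0 ± 48.1 (adjusted p = 0.00247, 0.00624 and 0.0073). Hspa5, a chaperone of the endoplasmic reticulum, was higher in ovary (128 ± 32.0 against 38.9 ± 16.1, adjusted p = 0.00618), as were hspa8 and dusp1, named after their values were seen. Of 20 genes, 6 were higher in testis, 3 in ovary and 11 not called, with as many adjusted over the list alone, and 1 was higher in ovary without ovary replicate 2 or 3 or testis replicate 2 (5 with DESeq2, quantile normalization, array weights and limma without trend). Of 59 transcripts, 7 were higher in testis, none in ovary and 52 not called (7 and 1 adjusted over the list alone). This list was not called (camera adjusted p = 0.244).

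Markers of blood cells went both ways. Ctss, a protease of phagocytes, stood at 3015 ± 686 in ovary and 46.2 ± 35.7 in testis and cybb, of the phagocyte oxidase, at 5.64 ± 2.17 and 0.487 ± 0.285 (adjusted p = 0.00289 and 0.00604). Coro1a, an actin regulator of leukocytes, stood at 0.193 ± 0.0929 and 9.53 ± 0.526 and itgb2, a leukocyte integrin, at 3.60 ± 1.07 and 32.1 ± 3.83 (adjusted p = 0.00235 and 0.00122). Of 11 leukocyte genes with a symbol, 5 were higher in testis, with zap70, lyz and cd74 named after their values were seen, 4 in ovary, with mrc1 and arhgdib named likewise, and 2 not called, with as many adjusted over the list alone, and none of 5 further transcripts without a symbol was called. Those higher in testis were 2 without ovary replicate 1 and 3 without ovary replicates 2 or 3 or testis replicates 2 or 3, with limma on log2(TPM + 1) and with a mean of at least 5 CPM. Of 7 red cell genes, cahz, tfrc and hbb1 were higher in testis, ank1 and nt5c3a in ovary and alas2 and epb41 not called (4 and 3 adjusted over the list alone). Hbb1, alas2 and epb41 were named after their values were seen. Of the red cell genes only cahz was higher in testis without ovary replicate 2 or 3 and with limma on log2(TPM + 1), when tfrc had adjusted p = 0.0688, 0.0600 and 0.133. Nt5c3a was not called without ovary replicate 1 or testis replicate 1 (0.0606 and 0.0534). Of 23 leukocyte transcripts, 2 were higher in testis, 2 in ovary and 19 not called (6 and 5 adjusted over the list alone), and of 23 red cell transcripts 3 were higher in testis, none in ovary and 20 not called (4 and 2 adjusted over the list alone). Neither list was called (camera adjusted p = 0.674 and 0.164).

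Smooth muscle genes were higher in testis for 6 of 11, higher in ovary for 1, mylk, and not called for 4, with as many adjusted over the list alone. Those higher in testis were 3 with limma-voom and 4 with limma on log2(TPM + 1). Tagln, an actin-binding protein of smooth muscle, stood at 6.64 ± 1.03 in ovary and 129 ± 107 in testis and smtn at 1.48 ± 0.488 and 10.5 ± 2.81, whereas mylk, the myosin light chain kinase, stood at 167 ± 31.9 and 25.4 ± 10.7 (adjusted p = 0.00519, 0.00348 and 0.00413). Of 7 skeletal muscle genes, tnni2 and acta1, of the sarcomere, were higher in testis, pygm, of glycogen breakdown, in ovary and 4 not called, with as many adjusted over the list alone, and 4 were higher in testis without testis replicate 2. Acta1 was not called with limma-voom or limma on log2(TPM + 1) (adjusted p = 0.0629 and 0.0523). Of 29 smooth muscle transcripts, 5 were higher in testis, 2 in ovary and 22 not called (12 and 2 adjusted over the list alone), and of 11 skeletal muscle transcripts 2, 1 and 8 (4 and 2 adjusted over the list alone). Neither list was called (camera adjusted p = 0.161 and 0.791), but smooth muscle was called higher in testis without testis replicate 2 (adjusted p = 0.0103). In ovary 2 of its genes were higher without testis replicate 1, a library in which its members stood above the other testes by a median of 1.42.

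Among the markers of surface epithelium, krt18, a keratin of simple epithelia, stood at 23 ± 1.28 in ovary and 643 ± 480 in testis, tp63, of stratified epithelia, at 0.970 ± 0.393 and 29.0 ± 26.8, and cldn7a, a tight junction protein, at 38.6 ± 26.2 and 0.437 ± 0.395 (adjusted p = 0.00375, 0.00369 and 0.00493). Of 11 genes, 3 were higher in testis, with krt8, 3 in ovary, with grhl2 and cldn7b, and 5 not called, with as many adjusted over the list alone. Krt8 and cldn7b were named after their values were seen. Those higher in ovary were 1 without ovary replicates 1, 2 or 3, when grhl2 had adjusted p = 0.0590, 0.0573 and 0.0522, and 5 without testis replicate 2. They were 7 with quantile normalization, 6 with limma on log2(TPM + 1), with array weights and without trend, and 5 with DESeq2 and limma-voom. Of 77 transcripts, 9 were higher in testis, 2 in ovary and 66 not called (12 and 7 adjusted over the list alone), with a camera adjusted p of 0.00722 toward ovary. The epithelial list had adjusted p = 0.466 with an estimated correlation and 0.347 with counts summed per gene.

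Of 9 adipocyte genes, pparg and cebpa, transcription factors of fat cells, were higher in testis, cidec and dgat2, of fat storage, in ovary and 5 not called, with as many adjusted over the list alone. Pparg was not called without ovary replicates 1, 2 or 3 or testis replicate 3 (adjusted p = 0.0571, 0.0572, 0.0548 and 0.0720), nor cebpa without ovary replicates 1, 2 or 3 or testis replicates 2 or 3 (0.151, 0.140, 0.132, 0.146 and 0.131), and cebpa was called in 7 of 19 alternatives in all. With limma on log2(FPKM + 1), limma on log2(TPM + 1), limma-voom, quantile normalization and no filter it had 0.0554, 0.138, 0.0869, 0.107 and 0.0714. Of 5 genes of liver, kng1, a kininogen, was higher in testis, cp, ceruloplasmin, in ovary, and a2m, fetub and itih2, the last named after its value was seen, were not called, and none passed adjusted over the list alone. Kng1 was not called without ovary replicates 1, 2 or 3 or testis replicates 2 or 3 (0.110, 0.0940, 0.141, 0.0548 and 0.140). It was called in 6 of 20 alternatives in all, and not with limma on log2(FPKM + 1), limma on log2(TPM + 1) or limma-voom (0.0805, 0.149 and 0.0540). Cp was not called without ovary replicates 1, 2 or 3 or testis replicates 1 or 3 (0.0817, 0.0598, 0.0808, 0.0525 and 0.0896), while a2m was called without testis replicate 1 (0.0121) and fetub without ovary replicate 3 (0.0425) and in 10 of 20 alternatives in all. Of 21 adipocyte transcripts, none was higher in testis, 2 in ovary and 19 not called (2 and 5 adjusted over the list alone), and of 21 liver transcripts 1, none and 20 (1 and none adjusted over the list alone). Neither list was called (camera adjusted p = 0.164 and 0.892).

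Too few markers of endothelium and nerve were tested for a list test. Of 2 endothelial genes, sox18, a factor of vessel growth, was higher in testis, at 7.56 ± 6.29 against 0.217 ± 0.107 (adjusted p = 0.00594), and vwf was not called (0.0727, and 0.0370 without testis replicate 1, called in 7 of 20 alternatives), while both passed adjusted over the list alone. Of 2 nerve genes, mbp, of myelin, was higher in testis, at 6.17 ± 2.77 against 0.997 ± 0.414 (adjusted p = 0.0173), and th, of catecholamine synthesis, in ovary, at 15.9 ± 7.54 against 1.04 ± 0.399 (0.0033), with as many adjusted over the list alone. Mbp was not called without ovary replicates 1 or 3 or testis replicates 2 or 3 (adjusted p = 0.0505, 0.0548, 0.0555 and 0.0731). Of the 2 endothelial transcripts, 1 was higher in testis and 1 not called (1 and none adjusted over the list alone), and of the 3 nerve transcripts none was called (1 and 1 adjusted over the list alone).

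By FPKM, the most abundant genes of the ovary were zp3, zp4 and mta, a metallothionein, which stood at 13813 ± 3505 in ovary and 2299 ± 1683 in testis (adjusted p = 0.0306). Those of the testis were rplp2 (29407 ± 17782, and 3969 ± 524 in ovary), rps21 (16951 ± 12621 and 823 ± 344) and rpl27a (15407 ± 9965 and 2598 ± 697), all of the ribosome (adjusted p = 0.0147, 0.0101 and 0.0217). Rps21 had 1269 counts over the testes, against 202420 for rpl15, and was not called with limma-voom (adjusted p = 0.110). Mta was not called without ovary replicates 1, 2 or 3 or testis replicates 2 or 3 (adjusted p = 0.0758, 0.0622, 0.0862, 0.0557 and 0.0732), rplp2 without ovary replicates 1, 2 or 3 (0.0613, 0.0655 and 0.0686), nor rpl27a without ovary replicates 1, 2 or 3 or testis replicates 2 or 3 (0.0970, 0.0879, 0.0664, 0.0644 and 0.0729). Zp3 was not called without ovary replicates 1, 2 or 3 or testis replicate 3 (0.0910, 0.0732, 0.0918 and 0.121), and zp4, among the fits with 1 library left out, was called only without testis replicate 2 (0.0140).

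Genes at 1 FPKM or more in all 3 libraries of one tissue and under 0.1 FPKM in all 3 of the other numbered 107 in testis and 36 in ovary, of which 49 and 5 had a symbol. They were 87 and 65 with TPM in place of FPKM, and 83 and 56 with limits of 0.5 and 0.05. They included rec8 and c9orf84 of the meiosis list, cfap69 of the flagellum list, star, and bgn, a matrix proteoglycan, in testis, and mrc1, a receptor of macrophages, in ovary, where c9orf84, cfap69, bgn and mrc1 were named after their values were seen. Transcripts of this kind numbered 308 in testis and 188 in ovary, or 240 and 269 with TPM in place of FPKM. Leaving out a library can only keep or raise these counts, since fewer libraries must then meet the limit. Their rise therefore does not show whether they rest on single libraries. The ovary genes were 57, 55, 62, 61 and 96 without ovary replicates 1, 2 and 3, testis replicate 3 and testis replicate 2. The ovary transcripts were 296, 316, 373, 423 and 285 without ovary replicates 2 and 3 and testis replicates 1, 2 and 3, and the testis transcripts 481 without ovary replicate 1. The number of genes at 1 FPKM or more was 10260 ± 259 in ovary and 10800 ± 113 in testis (exact two-sided permutation p = 0.1). Summed FPKM ran from 721650 to 821037 in the ovaries and were 770032, 1218425 and 1312673 in testis replicates 1, 2 and 3. The limit of 1 FPKM is therefore not alike across libraries, and this number was not taken with TPM.

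Of 1080 annotation terms tested over transcripts, Ribosome (camera adjusted p = 0.0193) and regulation of microtubule polymerization or depolymerization (0.0193) were called higher in testis and 6 terms higher in ovary. With counts summed per gene, Ribosome (adjusted p = 0.0178) and chromatin remodeling (0.0461) were called higher in testis, and Lysosome (0.0178), Vibrio cholerae infection (0.0178), DNA integration (0.0284) and serine-type peptidase activity (0.0461) higher in ovary. Among genes called higher in testis, Ribosome was over-represented (59 of its 102 genes, one-sided Fisher exact adjusted p = 2.99e-11) and so was chromatin remodeling (11 of 14, adjusted p = 0.00267). Over transcripts Ribosome was not over-represented (11 of 181, adjusted p = 1). With an estimated correlation camera called 0 terms at either level, with 55 and 16 at an unadjusted p under 0.05. Over transcripts, 3 and 10 terms were higher in ovary without ovary replicate 1 and testis replicate 1, and 4 were higher in testis without ovary replicate 3 or testis replicate 1. Over genes, those higher in testis were 1 without ovary replicates 1 or 2 or testis replicate 1 and none without testis replicates 2 or 3, while 2 were higher in ovary without testis replicate 1.

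Transcripts without any annotation were called higher in testis more often than annotated ones. Of 1017 tested, 197 or 19.4% were higher in testis, against 5.81% of the annotated transcripts (two-sided Fisher exact p = 2.46e-47), and 5.11% were higher in ovary, against 4.37% (p = 0.244). Of the transcripts built from testis long reads 15.8% were higher in testis, against 0.933% of those built from ovary long reads. In the other direction 0.952% and 6.33% were higher in ovary (two-sided Fisher exact p = 1.48e-133), so calls went with the tissue a transcript was built from. These Fisher tests take transcripts of the same libraries as independent, which they are not, so their p values do not measure variation between fish. The contrast by annotation was not split by the tissue a transcript was built from. Across transcripts, fold change and transcript length had a rank correlation of 0.0499, where transcripts are not independent replicates. When transcripts were parted by length into 3 classes of 10246, the long class held 703 higher in testis and 259 higher in ovary, and the short class 710 and 666.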

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

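The counts per gene, the sets found in one tissue at gene level, the fit without ribosomal protein and egg envelope transcripts, and the list and term tests per gene were chosen only after the data were seen. No named gene turned its direction under any setting, and with a replicate block 111 of 122 named genes kept their side of the threshold. Depth limits the folds of genes with at most 3 counts in one tissue, whose counting intervals are wide (rec8, 884 to 12540).

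Transcripts called, 3276 as reported, were 5618 and 5143 by limma on log2 FPKM with pseudocounts of 0.1 and 0.01, 1570 with no filter, 9907 with DESeq2, 6135 with quantile normalization, 5768 by limma without trend, 8563 with array weights, 2076 by limma-voom, and 5644 as genes. At an adjusted p under 0.01 edgeR called 0 transcripts, where limma-voom called 0, DESeq2 7069, and 9561 had an unadjusted p under 0.05, and 2997 genes. With the replicate block, though the numbers pair no fish, edgeR called 0 transcripts (7300 with an unadjusted p under 0.05) and 4370 genes. Leaving out 1 library gave 0 to 1439 transcripts (7992 to 9521 with an unadjusted p under 0.05). A fit with 1 library left out rests on fewer samples, and otherwise the cause was not tested.

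Found in one tissue, leaving out 1 library gave 356 to 481 transcripts in testis and 279 to 423 in ovary, as fewer libraries must meet the limit, and summing per gene gave 107 and 36. Terms ranged from 2 to 4 in testis and 3 to 10 in ovary on leaving out 1 library. They were 0 and 0 with an estimated correlation (55 with an unadjusted p under 0.05), and 5 in testis with terms of 5 to 500 members.

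With an estimated correlation the lists had adjusted p = 0.275 (egg envelope, oocyte, flagellum), 0.257 (meiosis, lipid), 0.278 (testis somatic), 0.354 (matrix), 0.365 (mitochondrial) and 0.466 (ribosomal, surface epithelium, Wnt). Fry asks whether a list's members move on balance one way, not whether they differ from other genes, and its adjusted p was 0.0683 (Wnt), 0.145 (surface epithelium), 0.0527 (ribosomal), 0.0303 (receptors), 0.0448 (adipocyte) and 0.0242 (erythrocyte). The Wnt list had 0.0692 on log2(FPKM + 0.1). Per gene camera gave 0.406 (Wnt), 0.774 (lipid), 0.347 (surface epithelium). Leaving out 1 library gave ranges of 0.0165 to 0.108 (Wnt), 0.0323 to 0.432 (cell cycle), 0.0103 to 0.291 (smooth muscle), 0.00845 to 0.236 (ovary somatic), 0.544 to 0.827 (leukocyte), 0.424 to 0.942 (liver) and 0.408 to 0.827 (skeletal muscle). The cause was not tested.

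Lists that were not called turned direction without being called. Over transcripts these were erythrocyte per gene (0.996), leukocyte with no filter (0.938) and without testis replicate 1 (0.827), liver with the replicate block (0.972) and without ovary replicates 1 and 3 and testis replicate 2 (0.942, 0.926, 0.687), and skeletal muscle without testis replicate 1 (0.827). Over genes these were adipocyte without ovary replicate 1 (0.994, range on leaving out 1 library 0.631 to 0.994), erythrocyte with no filter (0.997), DESeq2 size factors (0.977), quantile normalization (0.930), the block (0.988) and without ovary replicate 3 and testis replicate 1 (0.976, 0.702, range 0.702 to 0.994), leukocyte without testis replicate 1 (0.785, range 0.785 to 0.968) and by fry (0.877), and skeletal muscle with quantile normalization (0.930). The cause was not tested.

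On leaving out 1 library, the percent of counts in the 100 highest transcripts, testis minus ovary, ran from -4.59 to 4.02, and the percent of counts in the 1000 highest transcripts, testis minus ovary, from -5.72 to 1.10, each highest without testis replicate 1. The mean rank correlation between tissues was 0.302 with no filter and 0.4997 over genes, and over genes it was 0.910 between ovaries and 0.830 between testes. The cause was not tested.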

Other observations

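The tests of ovary RNA mixed into testis replicate 2, of reads of other genes, of library size and of muscle tissue, and the counts over splits for transcripts, genes, lists and terms over transcripts were chosen only after the result was seen.

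The shares of blood cell markers followed single genes. Leukocyte markers took 0.368% ± 0.0443 of the counts in ovary and 0.0485% ± 0.0179 in testis, and red cell markers 0.0294% ± 0.00225 and 0.344% ± 0.356 (SD, n = 3, exact two-sided permutation p = 0.1 for each, the smallest possible). Ctss held 92.3% of the leukocyte marker counts in ovary and cahz 73.3% of the red cell marker counts in testis. Red cell markers took 0.754% of the counts in testis replicate 1, 0.172% in replicate 2 and 0.106% in replicate 3.

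The testes also differed from one another. Set against the mean of the other two testes, testis replicate 1 held more of 46 of 50 flagellum genes, 34 of 37 meiosis genes, 43 of 45 cell cycle genes and 5 of 5 mitochondrially encoded genes (median log2 ratio 1.86, 1.15, 1.76 and 4.02), and less of 69 of 70 ribosomal protein genes, 27 of 30 members of the oocyte list and 19 of 27 matrix genes (median -1.39, -2.30 and -1.28). Of the 22 oocyte genes with a symbol it held less of 19 (median -1.31). This difference, with 1 fish on one side, was not tested.

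Egg envelope genes stood at 2.83% to 18.7% of their ovary mean in testis replicate 2, with a median of 11.99%. In replicate 3 their median was 0.366%, with zp3 at 6.84%. If ovary RNA had been mixed in, other abundant ovary genes that replicate 1 lacks should stand at a like percentage, and the median of 84 such genes was 3.84%, a ratio of 0.320 to the egg envelope genes, but 54 of the 84 reached the lowest egg envelope gene, so this cannot be told apart from expression in that testis. Carry-over of reads from the 3 sequenced ovaries is argued against as the whole pattern. In replicate 2, 47.6% of the egg envelope counts lay in transcripts whose share was over 10 times that in every ovary. An ovary held 16.7% to 24.7% of such counts against the other ovaries, and testis replicate 3 held 92.8%. Counts of a testis's own can raise this measure, so carry-over of a part of the counts remains open. Whether reads of other genes were assigned to egg envelope transcripts could not be decided. The oocyte list was higher in replicate 2 than in replicate 1, by a median of 2.03 on the log2 scale and in 28 of 30 members (1.65 and 20 of 22 for those with a symbol). Replicate 1 was also below the mean of the other testes in 27 of 30 members. Oocyte genes do not show the origin of the egg envelope reads. Tissue of an ovary other than those sequenced, or oocytes in that testis, may remain as well. The labels give no group that would test a biological explanation.

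Testis replicate 1 correlated less with the other testes than they did with each other. Library size is argued against, as its total was at most 1.14 times that of another testis. Unequal shares of ribosomal protein transcripts could not be weighed as a cause. Without the 70 ribosomal protein genes the correlation of replicate 1 with replicate 2 was 0.786, against 0.919 between replicates 2 and 3. A rank correlation over the other 12011 genes does not change with scaling, and leaving out 70 genes can hardly move it. Muscle tissue in the sample is argued against as the whole cause, since flagellum genes were higher there by a median of 1.86 on the log2 scale, against 1.42 for smooth muscle genes. A difference in the stage of the germ cells between fish may remain, and as the labels give no stage no biological explanation was tested.

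Transcripts varied between fish of one tissue more than genes did. Low counts are argued against as the whole cause, since transcripts with a mean of 1000 counts or more correlated at 0.625, against 0.870 for genes. At a mean of 100 to 1000 counts, transcripts that were the sole ones of their symbol correlated at 0.752 and those of symbols with 5 or more transcripts at 0.359, a difference of 0.393. This is consistent with near-identical transcripts sharing a gene's reads differently in each fish, a candidate explanation that was tested on the same data. No biological explanation was tested, and sequence differences between fish remain open.

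The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3276 transcripts and 5644 genes with edgeR, and each of the other splits 0 (at most 1018 and 298 with an unadjusted p under 0.05), so 1 of the 10 splits gave as many in each case. Each other split put both tissues in both groups, where the difference between tissues counts as spread within a group. Their 0 calls are therefore no measure of what chance gives. For the fixed lists the real split gave 11 calls over transcripts and the highest other 8, with 1 of the 10 splits giving as many, and over genes 7 against 8, with 3 of the 10 giving as many. For annotation terms it gave 8 calls over transcripts against 1, with 1 of the 10 giving as many, and over genes 6 against 15, with 5 of the 10 giving as many. A split that put testis replicate 3 with ovary replicates 1 and 2 gave these 15 terms.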
